A study of Homo sapiens with 8 samples.

How the data were processed

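RNA sequencing was done on CD34-positive cells, the surface marker of blood stem and progenitor cells, taken from the blood mononuclear cells of patients with a myeloproliferative neoplasm, a blood cancer of the stem cell. The series has 8 libraries, each from a different patient. Per the labels, 3 libraries were IL8 high and 5 were IL8 low, where IL8 is the older name of the chemokine CXCL8. All 3 IL8 high libraries and 2 of the IL8 low libraries came from patients with myelofibrosis (MF), and 3 IL8 low libraries came from patients with essential thrombocythemia or polycythemia vera (ET or PV). How IL8 status was assigned is not given in the sources used here.

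Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made with an Illumina TruSeq RNA kit. STAR 2.4, HTSeq 0.6.1, DESeq2 without a version and the genome build hg19 are named in the submitters' processing notes, without their roles. The annotation and the strand setting are not given in the sources used here. The deposited values are raw read counts per gene symbol from the authors, 1 column per library. The table had 55765 genes. XIST, TSIX and genes on chromosome Y, 436 in all, were removed before any other step, and all totals below are without them.

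Library totals were 12609541 to 16408737 counts in the IL8 high group and 4024690 to 10240874 counts in the IL8 low group. Every IL8 high library was deeper than every IL8 low library (two-sided exact permutation p = 0.0179, the smallest that the 56 splits of 8 libraries into 3 and 5 allow). CPM values, counts scaled to the same total in every library, were computed from these totals. Intervals and floors cover counting error only, because reads without molecular identifiers are not independent molecules.

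Each comparison was tested with edgeR 4.0.16 in R 4.3.3: low counts were filtered with filterByExpr on the 3 groups (minimum count 10, minimum total 15), libraries were scaled with TMM factors, and a robust quasi-likelihood F test was applied, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. This left 35229 genes. IL8 high was compared with IL8 low over all 8 libraries. A model with the 3 groups gave IL8 high MF against IL8 low MF and IL8 low MF against IL8 low ET or PV. CPM values are given as mean ± SD and log2 fold changes with their standard error (SE).

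A total of 21 gene lists was fixed before the data were examined, with 617 of their 618 entries in the table. They covered the CXCL8-CXCR axis, TNF and NF-kB targets, inflammatory cytokines and receptors, S100 alarmins, immediate early and AP-1 genes, JAK-STAT targets, interferon-stimulated genes, fibrosis-linked secreted factors, and heat shock, hypoxia and glycolysis, cell cycle, ribosomal protein and mitochondrially encoded genes. Marker lists covered megakaryocytes and platelets, erythroid cells, haematopoietic stem cells, granulocyte-monocyte progenitors, mature neutrophils, monocytes, T and NK cells, and B cells and lymphoid progenitors. Lists were tested with camera in limma 3.58.1 (preset correlation 0.01), and again with an estimated correlation and with fry. The camera p quoted for a list is the one with an estimated correlation unless the preset is named. The median log2 level of each list per library was also compared by an exact permutation test, with libraries scaled on above-background genes. These medians were taken over all members in the table, also those near background.

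The named genes followed a rule fixed before the data were examined. It took CXCL8, CXCR1 and CXCR2, then the 10 genes with the largest change in each direction among those past the threshold with a mean CPM of at least 1 and no overlap between the groups, and up to 4 members of each list with the smallest p, or 2 where no member passed. Pseudogenes, antisense genes, HLA and immunoglobulin genes and genes with common deletions were passed over.

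Gene types and transcript lengths came from GENCODE 29, an annotation of another build than hg19, so no positions are given. Of the table's names, 35246 matched it directly or through an older symbol or synonym and 20519 did not. After the data were examined, the 379 protein-coding olfactory receptor genes were taken as a measure of background, since blood progenitors are not known to use most of them. Above-background genes were defined as protein-coding genes with at least 10 times the CPM per kilobase of the olfactory receptor genes, averaged over the 8 libraries, which gave 7792 genes. All comparisons were repeated on these alone.

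Other settings fixed before the data were examined were RLE size factors, no filter beyond a total count above 0, a stricter filter (CPM of at least 1 in at least 3 libraries), the DESeq2 1.42.0 Wald test, limma voom with sample quality weights, other designs and leaving out each library. Settings added after the data were examined were library totals without scaling factors, TMM factors from above-background genes, above-background genes only, and the monocyte marker level as a covariate. The model was tested on simulated counts for IL8 high against IL8 low, drawn from the real means and spreads. Simulated totals were the real totals times their TMM factors, so the real gap in depth between the groups was not kept. After the filter 33259 genes were left, with 50 changed genes at each of 4 sizes. The model recovered 6% of the genes changed 2-fold, 50% at 4-fold, 94% at 8-fold and 100% at 16-fold, with 10 unchanged genes among 135 calls. The changed genes had a mean CPM of at least 5, and genes were drawn independently. Neither a background difference between the groups nor their real gap in depth was simulated, so these shares need not hold for the real libraries.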

Results

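The study measured gene expression in circulating CD34-positive cells of patients with myeloproliferative neoplasms, in connection with CXCL8 signalling and fibrosis of the bone marrow. The 3 libraries labelled IL8 high held 12609541, 15217901 and 16408737 counts. The 5 libraries labelled IL8 low held 7932876, 4024690, 7111913, 10240874 and 8576438 counts. Spearman correlations between pairs of libraries ran from 0.761 to 0.933, so no library was a copy of another. The olfactory receptor genes summed to 171 ± 41.2 CPM in IL8 high libraries (SD, n = 3) and 651 ± 212 CPM in IL8 low libraries (n = 5), without overlap (two-sided exact permutation p = 0.0179). Genes with at least 1 count numbered 42358 on average in IL8 high libraries and 48258 in IL8 low libraries, although the IL8 low libraries were shallower.

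The first question was how CD34-positive cells labelled IL8 high differed from those labelled IL8 low. CXCL8, the neutrophil-attracting chemokine listed in the table as IL8, stood at 383 ± 349 CPM (SD, n = 3) against 16.97 ± 18.1 CPM (n = 5), a log2 fold change of 5.38 (SE 1.21, edgeR adjusted p = 0.0434). The level of 1 of the 3 libraries labelled IL8 high lay within the IL8 low range of 6.33 to 49.2 CPM. The receptors CXCR1 (log2 fold change -0.73, SE 0.99, adjusted p = 0.603) and CXCR2 (0.10, SE 0.74, adjusted p = 0.929) did not pass the threshold. Without IL8 high replicate 1 both were lower past the threshold, CXCR1 at -4.22 (adjusted p = 0.0278) and CXCR2 at -2.04 (adjusted p = 0.0451), as were 5306 of the 7485 genes called in that omission. CXCR1 and CXCR2 lay at 1.401 and 3.96 times the olfactory receptor density in IL8 low libraries, near background, and the sign for CXCR2 turned under several other alternatives. Of the 9 CXCL8-CXCR axis genes, 1 passed the threshold, over all genes and also adjusted over the list alone (camera adjusted p = 0.823). The CXCL8 call was lost in 10 of 18 alternatives, with adjusted p from 0.000852 to 0.138 and log2 fold changes from 3.63 to 6.42. The fold change was 4.70 without IL8 high replicate 1 and 6.42 without IL8 low replicate 5. It was lost without IL8 high replicate 2 (0.0947) and without IL8 low replicate 1 (0.110), 2 (0.0986), 3 (0.134) or 4 (0.0579).

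**Figure D1:**
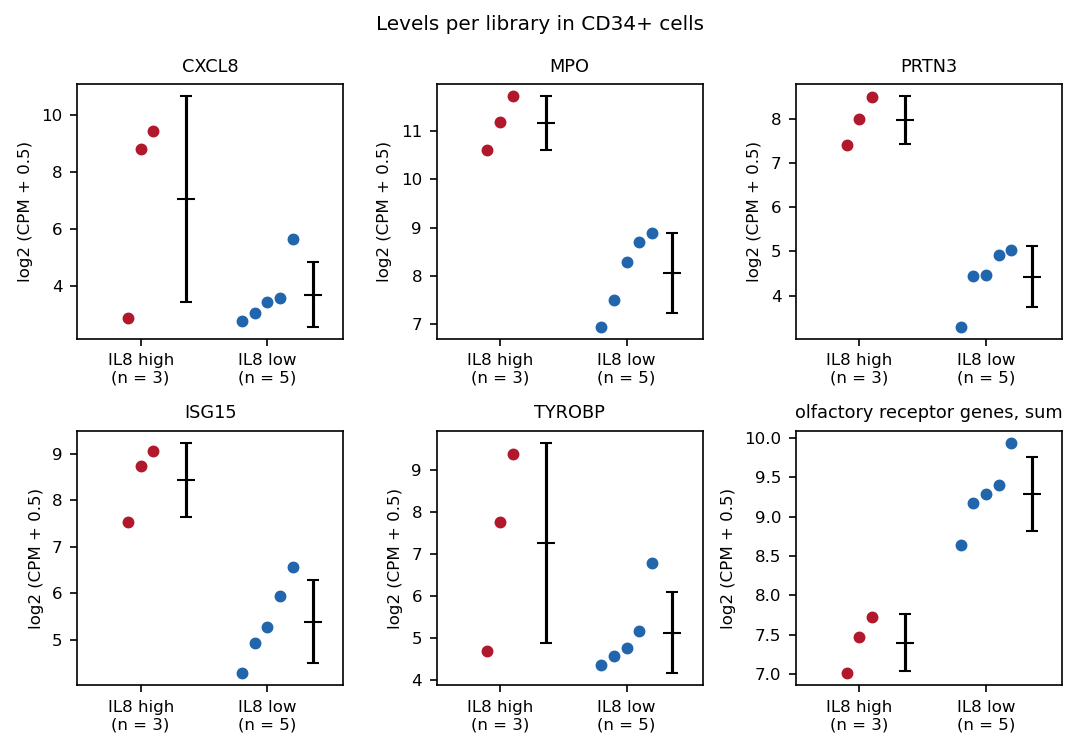
Level of 5 genes and of the summed olfactory receptor genes in each library, as log2 (CPM + 0.5), ordered by value within a group. Bars give the mean and SD. MPO lay between 10.61 and 11.72 in the 3 IL8 high libraries and between 6.94 and 8.88 in the 5 IL8 low libraries, whereas the CXCL8 and TYROBP levels of the groups overlapped.

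The clearest difference was in genes of neutrophil granules, which are transcribed in granulocyte-monocyte progenitors. MPO, the granule peroxidase, was at 2413 ± 908 CPM in IL8 high libraries (SD, n = 3) and 301 ± 150 CPM in IL8 low libraries (n = 5), a log2 fold change of 3.91 (SE 0.55, adjusted p = 0.0199). The serine protease gene PRTN3 rose by a log2 fold change of 4.55 (SE 0.43, adjusted p = 0.000530), from 22.8 ± 9.02 to 263 ± 96.1 CPM. AZU1, a related granule protein gene without protease activity, rose by 4.15 (adjusted p = 0.0111), and the protease gene CTSG by 3.55 (adjusted p = 0.0120). The eosinophil ribonuclease genes RNASE2 (4.0, adjusted p = 0.0139) and RNASE3 (3.62, adjusted p = 0.000530) rose too, and as close relatives they could share some reads. By the naming rule, which required no overlap, each of these 6 genes was higher in all 3 IL8 high libraries than in every IL8 low library. Of the 23 tested granulocyte-monocyte progenitor markers, 10 rose and none fell, and 16 rose when adjusted over the list alone. It was the 1 list of 21 that passed camera with an estimated correlation (adjusted p = 0.0101). Its median log2 level per library was 5.85 ± 0.24 against 4.09 ± 0.47, without overlap (two-sided exact permutation p = 0.0179, adjusted over 21 lists 0.25). PRTN3 passed in all 18 alternatives. Without IL8 high replicate 2 the adjusted p of MPO, CTSG and RNASE2 was 0.0705, 0.0687 and 0.0705. Without IL8 low replicate 1 it was 0.0741, 0.0780 and 0.0807 for these genes and 0.0741 for AZU1, and without IL8 low replicate 3 it was 0.0581 for MPO. On above-background genes alone it was 0.0598 for RNASE3 and 0.115 for RNASE2.

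Many interferon-stimulated genes were called, although the list did not pass as a group with an estimated correlation (adjusted p = 0.194). Of 34 tested members 24 rose and none fell, and 32 rose when adjusted over the list alone, but on above-background genes alone 1 of 33 rose. ISG15, a ubiquitin-like protein induced by interferon, rose from 48.2 ± 29.6 CPM (SD, n = 5) to 380 ± 176 CPM (n = 3), a log2 fold change of 3.87 (SE 0.58, adjusted p = 0.0247). OASL rose by 3.49 (adjusted p = 0.0236), IFITM3, a membrane protein that restricts virus entry, by 3.0 (adjusted p = 0.0384), and OAS2 by 2.87 (adjusted p = 0.0396). The preset camera test gave an adjusted p of 1.84e-29 for the list, and fry gave 0.0215. The per-library medians of the list overlapped between the groups (6.72 ± 0.77 against 5.40 ± 0.64, two-sided exact permutation p = 0.0536). Without IL8 high replicate 2, the adjusted p of ISG15, OASL, IFITM3 and OAS2 was 0.0906, and without IL8 low replicate 1 it was 0.110. Without IL8 low replicate 3, IFITM3 had 0.134 and OAS2 0.0656, and without IL8 low replicate 5 OAS2 had 0.0589. With limma voom IFITM3 and OAS2 had 0.0519, with equal weight of the IL8 low stages OAS2 had 0.0757, and on above-background genes alone OASL, IFITM3 and OAS2 had 0.0887, 0.0845 and 0.115.

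Calls among inflammatory genes were not matched by a shift of the whole lists in every IL8 high library. TNF and NF-kB targets had 15 of 47 members higher (28 adjusted over the list alone), among them PLAUR, the urokinase receptor (log2 fold change 4.22, adjusted p = 0.0375), and GADD45B (4.41, adjusted p = 0.0384). Of the inflammatory cytokines and receptors, 9 of 36 rose (21 adjusted over the list alone). OSM, a cytokine of the interleukin 6 family, went from 17.8 ± 6.79 CPM (SD, n = 5) to 72.6 ± 30.8 CPM (n = 3), and TNFSF13B and IL1B had log2 fold changes of 2.50 and 1.93 (adjusted p = 0.0384 and 0.0396). S100 alarmins, small calcium-binding proteins released in inflammation, had 4 of 8 members higher (5 adjusted over the list alone), including S100A4 (2.20) and S100A6 (2.21). Immediate early and AP-1 genes had 9 of 32 higher and none lower (24 higher and 1 lower adjusted over the list alone), among them ZFP36 (4.20, adjusted p = 0.0396) and ATF3 (2.82, adjusted p = 0.0404). JAK-STAT targets had 4 of 22 higher (7 adjusted over the list alone), with the feedback inhibitor SOCS3 at 3.02 (adjusted p = 0.0384). The adjusted p with an estimated correlation was 0.197 for each of these 5 lists. Their medians per library overlapped between the groups, with two-sided exact permutation p of 0.214 for TNF and NF-kB targets, 0.518 for inflammatory cytokines and receptors, 0.161 for S100 alarmins, 0.393 for immediate early genes and 0.946 for JAK-STAT targets (5.48 against 5.47). In IL8 high replicate 3 the median log2 level of TNF and NF-kB targets (3.49) and of inflammatory cytokines (2.60) lay below every IL8 low library (lowest 3.55 and 3.06). These medians took in members near background: 33 of 47 and 21 of 36 tested members of these lists were above-background genes. Higher background in IL8 low libraries could raise their medians, so the overlap does not exclude a shift of the expressed members. PLAUR, GADD45B, OSM and TNFSF13B passed in 12 of 18 alternatives and IL1B, S100A4 and S100A6 in 11. All 7 were lost without IL8 high replicate 2 (adjusted p = 0.0906) and without IL8 low replicate 1 (0.110) or 3 (0.106 to 0.134). ZFP36 passed in 10 of 18 alternatives and ATF3 in 7 of 17, and SOCS3 in 15 of 17. On above-background genes alone no member of these 5 lists passed. The list medians there were 0.82 for TNF and NF-kB targets, 1.25 for cytokines and receptors, 2.26 for S100 alarmins, 1.07 for immediate early genes and -0.15 for JAK-STAT targets. Monocyte markers moved with these groups: 6 of 29 rose (12 adjusted over the list alone), among them AIF1 (1.91, adjusted p = 0.0396) and TYROBP (3.69, adjusted p = 0.0408). TYROBP, a signalling adaptor of myeloid cells, was at 300 ± 325 CPM against 43.1 ± 37.9 CPM, and the monocyte list had an adjusted p of 0.352 with an estimated correlation. AIF1 passed in 9 and TYROBP in 6 of 18 alternatives.

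Markers of other blood cells showed few calls. Of 30 megakaryocyte and platelet markers and 33 erythroid markers none passed the threshold, also adjusted over the list alone. SPARC (log2 fold change 1.42, adjusted p = 0.0707), NFE2 (1.39, adjusted p = 0.0719), BLVRB (1.70, adjusted p = 0.0501) and SPTB (-1.33, adjusted p = 0.0739) had the smallest p. Among 31 haematopoietic stem cell markers SPINK2 rose (1.56, adjusted p = 0.0464) and LIN28B fell by 2.71 on the log2 scale (adjusted p = 0.0454), and LIN28B lay at 1.20 times the olfactory receptor density in IL8 low libraries. Of 39 fibrosis-linked secreted factors TIMP1, a metalloproteinase inhibitor (1.86, adjusted p = 0.0494), and VEGFB (1.49, adjusted p = 0.0491) rose, while adjusted over the list alone 3 rose and 5 fell. Among 27 mature neutrophil markers CSF3R rose (1.96, adjusted p = 0.0463), but none did adjusted over the list alone. CST7 (3.11, adjusted p = 0.0236), which is also on the granulocyte-monocyte list, was the single call among 32 T and NK cell markers, also adjusted over the list alone. CD79B (1.87, adjusted p = 0.0422) was the single call among 23 B cell and lymphoid progenitor markers (4 higher and 1 lower adjusted over the list alone). The adjusted p with an estimated correlation was 0.723 for megakaryocyte, 0.823 for erythroid, 0.574 for stem cell, 0.876 for fibrosis-linked, 0.857 for neutrophil, 0.971 for T and NK and 0.857 for B cell lists. The B cell list had a lower median per library in the IL8 high group (1.35 ± 1.39 against 2.96 ± 0.70, two-sided exact permutation p = 0.0357, adjusted over 21 lists 0.25), with overlap between the groups. In the fit of above-background genes, with 8 of its 23 tested members, the B cell list had a median log2 fold change of 1.01. The lower level is therefore not shown for its expressed members. The calls in this paragraph were often lost: SPINK2, CSF3R and TIMP1 passed in 7 of 18 alternatives, CD79B in 9 and CST7 in 14, and LIN28B passed in 9 and VEGFB in 5 of 17. None passed without IL8 high replicate 2, where adjusted p ran from 0.0906 (CST7) to 0.135 (TIMP1), or without IL8 low replicate 1 (0.110 to 0.120) or 3 (0.0927 to 0.143). On above-background genes alone the log2 fold change was 0.70 for SPINK2 (adjusted p = 0.285), 1.09 for TIMP1 (0.181) and 1.23 for CSF3R (0.146). It was 1.14 for CD79B (0.132) and 2.36 for CST7 (0.0598), so these calls were lost there.

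Among general cell programmes, ribosomal protein genes had 24 of 56 members higher (53 adjusted over the list alone), including RPS19 (log2 fold change 1.84) and RPL35 (1.58). Heat shock genes had 4 of 19 higher (13 higher and 1 lower adjusted over the list alone), including DNAJB1 (1.98) and HSPA1A (2.95), which could share reads with its near-identical neighbour. Of 26 hypoxia and glycolysis genes 2 rose (13 adjusted over the list alone), DDIT4 (3.08) and ALDOA (1.64). The cell cycle list had 1 of 36 higher (2 adjusted over the list alone), the mitotic kinase AURKB (2.11). The mitochondrially encoded list had 1 of 13 higher (13 adjusted over the list alone), MT-CO2 (1.52). The adjusted p with an estimated correlation was 0.197 for ribosomal protein, hypoxia and mitochondrial genes, 0.180 for heat shock and 0.352 for cell cycle genes. The fry adjusted p was 0.00468 for ribosomal protein and mitochondrial genes, 0.00895 for heat shock, 0.0673 for hypoxia and 0.183 for cell cycle genes. CRABP1, a retinoic acid binding protein (3.63, adjusted p = 0.0219), and HILPDA, a lipid droplet protein (3.51, adjusted p = 0.0384), belonged to no list and were the others of the 10 largest increases among genes without overlap between the groups. HILPDA was carried by 1 library: without IL8 high replicate 2 its log2 fold change was 1.89 (adjusted p = 0.0906), and it passed in 11 of 17 alternatives. RPL35 and ALDOA passed in 8 of 18 alternatives, MT-CO2 in 6, RPS19, AURKB and DNAJB1 in 10, DDIT4 in 11, HSPA1A in 12 and CRABP1 in 15. None of these 10 genes passed without IL8 high replicate 2 (adjusted p = 0.0906 to 0.129) or IL8 low replicate 1 (0.1004 to 0.120). On above-background genes alone no member of the ribosomal protein, heat shock, hypoxia, cell cycle or mitochondrial lists passed. With the median over all tested members in brackets, list medians there were 0.45 (1.35) for ribosomal protein and 0.58 (1.31) for heat shock genes. They were 0.69 (1.21) for hypoxia and glycolysis, 0.39 (0.95) for cell cycle and 0.43 (1.31) for mitochondrially encoded genes.

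The largest decreases were in genes read at very low levels. TCF21 and KIF2B had no count in the 3 IL8 high libraries. Against a floor of 3 counts over that group they were at least 25.3-fold and 24.7-fold lower, from 1.72 ± 0.875 and 1.67 ± 1.32 CPM in IL8 low libraries (SD, n = 5). PCDHAC2, CHRM1, CALHM1, OR7G1, CLPS, VAX1, SSTR1 and GPRC5D, genes of neurons, sense organs, pancreas and plasma cells among others, had log2 fold changes from -5.14 to -4.20 (adjusted p = 0.0396 to 0.0440). In IL8 low libraries these 10 genes stood at 0.509 to 4.68 times the read density of olfactory receptor genes. All 10 calls were lost with limma voom and with equal weight of the IL8 low stages. They were also lost without IL8 high replicate 2 and without IL8 low replicate 1 (adjusted p = 0.110) or 3 (0.134). CLPS passed in 8 of 15 alternatives, and GPRC5D, which passed most often, in 12 of 17.

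In all, 1762 of 35229 genes passed the edgeR threshold, 1006 higher and 756 lower in IL8 high libraries. In CPM from library totals the groups did not overlap in 13333 genes (37.8%), against 3.57% by chance for a single gene. Under that scaling most genes shifted together: 9757 of 9995 calls were lower, with a median log2 fold change of -1.44. The share is therefore not a count of independent differences. Among the higher genes 90.6% were protein coding, and among the lower genes 46.4% were protein coding, 12.7% pseudogenes and 32.0% of names without a match. The median log2 fold change was 0.81 in above-background genes and -1.07 in olfactory receptor genes, so changes of expressed genes are to be read against 0.81. On above-background genes alone, where the median was 0.02, 5 genes rose and 1 fell: PRTN3 (3.67), AZU1 (3.30), MPO (3.18), ISG15 (3.09) and CTSG (2.77) rose, and PTK2, the focal adhesion kinase gene, fell by 1.87 (SE 0.27, adjusted p = 0.0251). PTK2 was chosen after its values were seen. It was at 16.9 ± 4.15 against 65.1 ± 9.81 CPM, and over all genes its log2 fold change of -1.0 had an adjusted p of 0.0682. It passed in 4 of 18 alternatives, with log2 fold changes from -1.95 to -0.82 and adjusted p up to 0.190. In this fit the granulocyte-monocyte list kept a median of 1.67 (adjusted p = 0.0191 with an estimated correlation), the interferon list had 1.54 (adjusted p = 0.323), and the megakaryocyte, stem cell and JAK-STAT medians changed sign to -0.54, -0.25 and -0.15, as did those of the T and NK cell list (-0.38 to 0.44) and the B cell list (-0.26 to 1.01). These medians cover fewer genes, 28 of 30, 22 of 31, 17 of 22, 6 of 32 and 8 of 23 tested members in that order, so they are not medians of the same genes. The share of higher calls among all calls was 57.1% as reported, 70.8% with RLE factors, 2.38% with library totals and 6.37% with TMM factors from above-background genes. The count fell to 3 without IL8 high replicate 2 (RNASE3, PRTN3 and AZU1), to 2 without IL8 low replicate 1 (PRTN3 and RNASE3) and to 12 and 101 without IL8 low replicate 3 and 5, and rose to 7485 without IL8 high replicate 1.

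**Figure D2:**
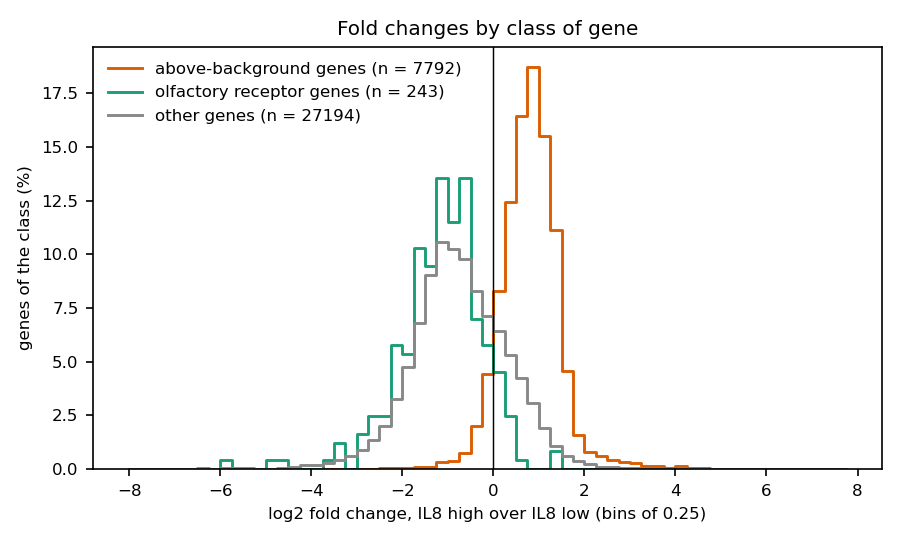
Distribution of log2 fold changes (IL8 high over IL8 low, bins of 0.25) as the percentage of genes in each class. Above-background genes centred at 0.81, olfactory receptor genes at -1.08 among those not above background, and the other genes at -0.78.

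**Figure D3:**
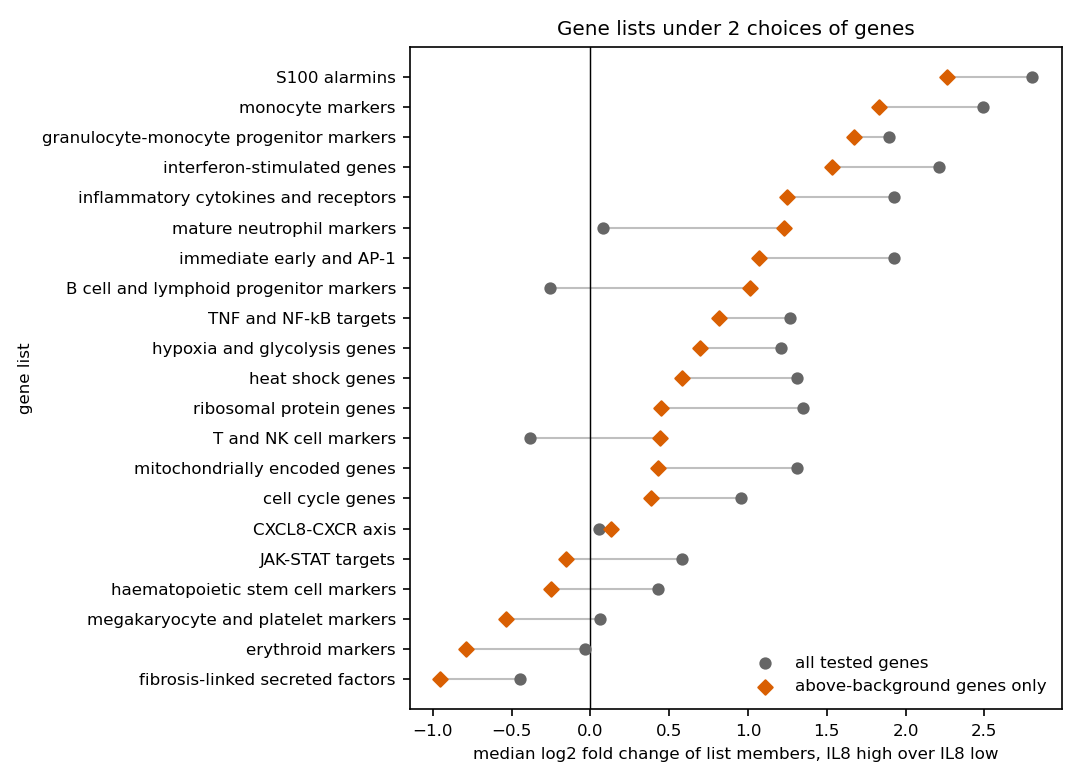
Median log2 fold change of each gene list, IL8 high over IL8 low, over all tested members (circles) and over above-background members in a fit of those genes alone (diamonds). The granulocyte-monocyte list moved from 1.90 to 1.67, and the megakaryocyte list from 0.06 to -0.54.

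The second comparison stayed within MF and set the 3 IL8 high MF libraries against the 2 IL8 low MF libraries. The type of MF was not matched between them. Per the sample titles, most IL8 high libraries came from primary MF, while the IL8 low MF libraries came from MF after ET or PV. Granule genes again had the smallest adjusted p: RNASE3 was at 28.3 ± 2.74 CPM (SD, n = 3) against 3.59 ± 0.294 CPM (n = 2), a log2 fold change of 3.87 (SE 0.52, edgeR adjusted p = 0.0961), and PRTN3 at 263 ± 96.1 against 21.3 ± 0.157 CPM (4.53, SE 0.69, adjusted p = 0.210). No gene passed the threshold, with 6015 genes at an unadjusted p under 0.05. The granulocyte-monocyte list passed as a group, with 17 of 23 members above 0, a median of 1.89, 11 higher adjusted over the list alone, camera adjusted p = 0.0228 with an estimated correlation and fry adjusted p = 0.0141. On above-background genes its adjusted p was 0.106. Monocyte markers had 27 of 29 members above 0 and a median of 1.83 (adjusted p = 0.511 with an estimated correlation). Their median log2 levels overlapped, at 7.95, 5.28 and 2.16 in IL8 high libraries and 3.22 and 6.35 in IL8 low MF libraries. Those of the granulocyte-monocyte list did not, at 6.12, 5.75 and 5.68 against 4.37 and 4.42. The interferon list had 34 of 34 members above 0 (median 1.83, 17 higher adjusted over the list alone), with ISG15 at 3.51 and OASL at 2.82, and the cell cycle list 36 of 36 (median 1.07), with AURKB at 2.80 and CCNB1 at 1.84. Ribosomal protein genes had 56 of 56 above 0 (median 1.5), with RPL35 at 1.84. On above-background genes alone the medians were smaller, 1.01 for interferon, 0.60 for cell cycle, 0.74 for ribosomal protein and 1.54 for granulocyte-monocyte genes. The preset camera test called 13 of 21 lists, but adjusted p with an estimated correlation was 0.251 for the interferon and ribosomal lists and 0.305 for the cell cycle list. With fry the ribosomal protein list (adjusted p = 0.0370) and the mitochondrially encoded list (0.0437) passed as well. DESeq2 called 1043 genes and limma voom 5. With no filter 2 genes passed, PRTN3 and RNASE3. Without IL8 low replicate 3 1 gene passed, the pseudogene HBBP1, named after its values were seen. That omission left 1 library in the IL8 low MF group, so the other groups supplied the spread.

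The third comparison asked whether stage alone was visible among IL8 low libraries, 2 MF against 3 ET or PV. No gene passed the threshold, with 288 at an unadjusted p under 0.05, so the following are values only. The interferon-stimulated genes had 34 of 34 members with a positive log2 fold change (median 1.05). OAS1 was at 74.3 ± 36.0 CPM (SD, n = 2) against 15.7 ± 3.41 CPM (n = 3) and IFITM1 at 38.0 ± 6.55 against 9.33 ± 3.90 CPM. AVP, a stem cell marker, was at 23.5 ± 18.6 against 3.40 ± 1.51 CPM, ID1 at 12.4 ± 8.31 against 0.997 ± 0.441 CPM, and CLEC7A, the beta-glucan receptor, at 64.0 ± 21.4 against 15.2 ± 5.36 CPM. Of the monocyte markers, 29 of 29 had a positive log2 fold change (median 1.73), and FCGR3A was at 77.9 ± 102 against 4.67 ± 2.41 CPM. This rested largely on 1 library: without IL8 low replicate 5 the log2 fold change of FCGR3A went from 4.36 to 0.34. S100A9 had a log2 fold change of 3.65 (SE 1.93), which turned to -1.47 without IL8 low replicate 5. The granulocyte-monocyte list had a median of 0.44, with CFD, the complement protease adipsin, at 44.1 ± 14.4 against 11.03 ± 5.56 CPM. Cell cycle genes had 5 of 36 members above 0 (median -0.39), with AURKB at 7.05 ± 3.22 against 14.8 ± 4.28 CPM. The preset camera test called 20 of 21 lists, and none passed with an estimated correlation (adjusted p = 0.150 for the interferon and granulocyte-monocyte lists and 0.293 for the monocyte list) or with fry. DESeq2 called 1 gene, ODF3B, named after its values were seen, and limma voom none. HBBP1 passed without IL8 low replicate 3, and 1 gene passed without IL8 low replicate 5. Each omission left 1 MF library, so the spread came from the other groups.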

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

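The rule that picks out a library far from the other 4 in the IL8 low group was applied to 83 values, of which 4.15 would be picked out by chance, and it picked out 7. The gap divided by the range was 0.719 for CXCL8, 0.743 for RNASE3, 0.772 for OASL, 0.755 for OSM, 0.719 for TIMP1, 0.740 for NFE2 and 0.785 for the median of the JAK-STAT targets, against a critical value of 0.71. All tests in the next paragraph were chosen after the result was seen.

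CXCL8 is weighed as a pattern because the groups are named after it. Across the 8 libraries CXCL8 followed the median of the monocyte markers, with Spearman's rho 0.929 (two-sided exact permutation p = 0.00223, adjusted over 4 relations 0.00893) and Pearson's r 0.862 (exact p = 0.00851), and r was 0.830 without the 2 libraries farthest from the median. RNA of monocytes in the CD34 selections may thus account for part of the CXCL8 level. With the monocyte level as a covariate, however, the difference between the groups went from 5.38 (SE 1.21) to 3.93 (SE 0.72) and stayed past the threshold (adjusted p = 0.0461). That fit is among the 18 alternatives, over which the adjusted p of CXCL8 ran from 0.000852 to 0.138. It was not itself repeated under the others. Activation of the cells during handling stays open, since rho with the immediate early genes was 0.571 (exact p = 0.151), while r was 0.754 (exact p = 0.0322, adjusted over 4 relations 0.0644) and 0.808 without the 2 libraries farthest from the median. IL8 status of the patient stays open too: 2 of the 3 libraries labelled IL8 high exceeded every IL8 low library, and how status was assigned is not given in the sources used here.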

How the results depend on the processing

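Between IL8 high and IL8 low, the 1762 calls became 2906 with RLE size factors, 5923 with DESeq2, 15 with limma voom, 17 with equal weight of the IL8 low stages, and, added after the data were examined, 9995 with library totals, 3264 with TMM factors from above-background genes and 6 with above-background genes only. Of these, 1736, 1755, 15, 16, 988, 962 and 5 were among the 1762. The 2 filters and the monocyte covariate gave 1871, 2271 and 1641. Leaving out 1 library gave 2 to 7485. Above-background genes were fewer and were scaled on themselves, and for the other settings the cause was not tested. With IL8 high MF against IL8 low MF, no filter gave 2 calls, DESeq2 1043, limma voom 5 and leaving out 1 library 0 to 1. With IL8 low MF against ET or PV, DESeq2 gave 1 and leaving out 1 library 0 to 1. Every other setting gave 0 in both. The 15, 13 and 20 lists called in the 3 comparisons became 1, 1 and 0 with an estimated correlation, 5, 3 and 0 with fry, and 1, 0 and 0 on above-background genes with an estimated correlation. Leaving out 1 library gave 13 to 18, 13 to 17 and 9 to 20. CXCR2 turned to -0.81 with TMM factors from above-background genes, -0.99 with library totals, -1.19 with limma voom, -1.56 with the monocyte covariate, and -2.04, -0.07 and -0.06 without IL8 high replicate 1, IL8 low replicate 1 and IL8 low replicate 4 (range over omissions -2.04 to 0.63). S100A9 among IL8 low libraries turned to -1.47 without IL8 low replicate 5 (range over omissions -1.47 to 4.63). No other gene recomputed under these settings changed direction; HBBP1 and ODF3B were not followed across them. No paired analysis was possible because each library came from a different patient. In simulated counts without a background difference or the real gap in depth between the groups, 50% of genes changed 4-fold were recovered. This limits what 3 against 5 libraries can show.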

Other observations

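The counts over splits of the libraries and the gene list tests within MF and by stage were planned, while the use of these list tests against stage, and the tests with the monocyte covariate, above-background genes, read density and genes with a count, were chosen after the result was seen.

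The granule genes higher in IL8 high libraries are the second pattern. RNA of monocytes in the CD34 selections is argued against as their whole source: with the monocyte marker level as a covariate, the list median was 1.74 against 1.90 without it, 11 members passed and the adjusted p with an estimated correlation was 0.0235, while the monocyte list itself went from 2.49 to 1.13. Whether background reads that dilute the IL8 low libraries have a part is not decided by the median of 1.67 among above-background genes. That class was set on all 8 libraries, so members could enter it through their IL8 high levels. RNASE3 was in it at 9.02 times the olfactory receptor density in IL8 low libraries. The 4 granule genes called in that fit, MPO, PRTN3, AZU1 and CTSG, stood at 15.3 to 126 times this density in IL8 low libraries. Fibrotic stage of the patients, taken as MF against ET or PV, is argued against as the whole cause. The median between IL8 high MF and IL8 low MF libraries was 1.89 (adjusted p = 0.0228 with an estimated correlation). On above-background genes alone it was 1.54, where all genes of that fit had a median of 0.05, but the list did not pass there (adjusted p = 0.106). The median SE of single members was 0.67, which is not an SE of the list median. A part for stage stays open, because the median between IL8 low MF and IL8 low ET or PV libraries was 0.44 with a median SE of single members of 0.64. The type of MF largely followed IL8 status among the MF libraries, so the comparison within MF cannot tell these apart. A larger share of granulocyte-monocyte progenitors was not tested.

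The genes lower in IL8 high libraries form the third pattern. Their median read density in IL8 low libraries was 3.85 times that of olfactory receptor genes (quartiles 2.39 and 5.31, over 514 genes with a length), against 30.6 times for the higher genes. Background reads that do not come from expressed genes, such as reads from genomic DNA or unspliced RNA, may therefore account for most of them. Lower depth of the IL8 low libraries is argued against as the whole cause, since the deeper IL8 high libraries had fewer genes with a count on average (difference -5899, two-sided exact permutation p = 0.0179). Background reads also raise the number of genes with a count, so a part for depth is not excluded. Lower expression in IL8 high progenitors stays open for genes this near background: 3 of the 351 protein-coding ones (0.855%) were above-background genes.

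Of the 56 splits of the 8 libraries, 1, the real one, gave 1762 calls, and the highest other gave 262. A single split is the smallest share that 56 splits allow. The real split also separated library depth and olfactory receptor reads without overlap, so this count cannot tie the calls to IL8 status. For above-background genes, 2 of 56 splits gave 6 calls or more. The highest other gave 128, many times the real count, and set apart 2 IL8 high and 1 IL8 low library, those with the highest monocyte marker medians, which points to a structure of the samples beside IL8 status. For the number of lists past the preset camera test chance cannot be excluded: 24 of 56 splits gave 15 or more, up to 20.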
